A study of Mus musculus with 12 samples.

How the data were processed

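Prostate RNA from paraquat-treated mice aged 4 months was selected for poly-A and prepared with a TruSeq kit for HiSeq2000 sequencing, per the labels' protocols, with 6 libraries from wild-type and 6 from null mice. The submitters' processing notes name CASAVA 1.8.2, TopHat, Cufflinks and DESeq with the builds mm9 and GRCm38.p2, without saying which step used which. The read layout, strand setting and handling of reads that map to several places are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. Gapdh, which has many processed pseudogenes, was listed at set means of 5.44 to 5.92.

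The deposited table holds log2 values, 1 per gene and library, already normalized by the authors between libraries. It has 39179 Ensembl gene IDs, of which 37607 (96.0%) matched a symbol and position in the GENCODE annotation of GRCm38. Values ran from -0.28 to 21.24. Of the genes, 18491 had a mean under 2.5 and formed a floor of unequal values with a median of 1.98 and an SD of 0.55. On the linear scale (2 to the power of the value), values from 2353 to 5793, 855 to 1071 per library, were used to find a factor and an offset per library. The value times the factor, less the offset, was within 0.1 of a whole number for 100% of them, against 20% by chance. The same held for 96.6% to 99.3% of the 233 to 419 values per library above that range and up to 65536, which were not used to find the factor. It held for only 17.8% to 21.4% of values a little lower, so counts could not be recovered for most genes and no count-based test was possible. The factors gave totals of 14.8 to 21.7 M reads per library. These totals are estimates, since values near the floor do not follow the same scale.

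A count-based test had been planned before the data were examined, with limma's trend method on log2 values as the stated substitute where a table held no counts. The substitute was used, without a further logarithm or pseudocount because the values are log2 already, and differences of low genes are understated on such a variance-stabilized scale. Genes with a value of at least 4 in 6 or more libraries were kept, which left 16197. The test was limma 3.58.1 in R 4.3.3 (trend, two-sided) with Benjamini-Hochberg adjustment over all genes tested, and calls were made at an adjusted p of 0.05. Python 3.11.15 was used for annotation, library summaries and figures.

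Libraries were compared in pairs by a chi-square of recovered reads over 723 genes, where sampling noise alone gives a median of 0.455. Medians were 0.987 to 5.71 within the sets of 3 libraries and 42.4 to 93.4 between sets of the same genotype. The libraries of a set thus differed by more than sampling noise and were not merged for the planned test. The sets were found by clustering the values within each genotype, not from the labels, with the number of clusters set to 2. The comparisons within and between sets use the same values as the clustering. The mean of each set was used as 1 replicate in a second limma fit (4 set means). The median SD was 0.104 within sets and 0.232 between sets of 1 genotype. On simulated data with 200 genes changed among 16197 and sets that did not differ, the fit over 12 libraries recovered 99% of changes of 1 and 100% of changes of 2 on the log2 scale, and the fit over set means 96% and 100%.

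Gene lists and the rule for named genes were fixed before the data were examined. The 33 lists, all described in the results, cover respiratory chain and mitochondrial genes, stress responses, prostate and seminal vesicle secretion, and markers of cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists, with an estimated correlation and fry as alternatives. Named genes are the 12 called genes per direction with the largest difference among those with a mean of at least 5 CPM, no overlap between genotypes and a symbol that is not a predicted-gene name, then up to 4 members of each list with the lowest limma p over the 12 libraries, in place of the planned count-based p. CPM was computed here from 2 to the power of the value. A gene named outside this rule is said to be so, and a few items that were planned are not reported here.

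Alternatives fixed before the data were examined were other scalings, filters, thresholds, library weights and leaving out each library. Those added afterwards were the set means, the set as a random block, leaving out each set, quantile normalization, a stricter filter, a damped log2 scale and removal of the transcript length trend. Transcript length is that of the longest annotated transcript of a gene.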

Results

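RNA was sequenced from the prostates of mice aged 4 months that had received paraquat, a herbicide that generates superoxide in cells and is used to induce oxidative stress. The series title concerns mitochondria. The mice were wild type or null for the gene under study on a hybrid 129/SvImJ and C57Bl/6J background. There were 6 libraries of each genotype and no libraries from untreated mice among those used here, so the comparison is between genotypes under paraquat and not between treated and untreated tissue. Values are the deposited normalized log2 values, and the depth recovered from them was 14.8 to 21.7 M reads per library, with a mean of 18.0 M reads in wild type and 17.8 M reads in the null. Each difference below is null minus wild type on that log2 scale.

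When the libraries of each genotype were clustered into 2 sets, they fell into sets of 3 with closely similar profiles, libraries 1 to 3 and libraries 4 to 6. The median absolute difference between libraries was 0.0776 to 0.141 within a set and 0.274 to 0.352 between sets of the same genotype. Nothing in the labels says which libraries came from separate animals, so p-values over the 12 libraries hold only if the libraries of a set are independent. Results are therefore given both over the 12 libraries (limma, n = 6 per genotype) and over the means of the sets (limma, n = 2 per genotype), an analysis chosen after the sets were seen. The words rose, fell and changed are used of single genes only where both passed an adjusted p of 0.05. Standard errors (SE) are limma's moderated ones from the fit over the set means, drawn toward a trend over all genes. For genes whose sets of 1 genotype disagree most, such an SE can be smaller than their own set means alone would give.

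Among the gene lists, prostate secretory products were lower in the null, and seminal vesicle products and interferon-response genes were higher, under camera with the preset and with an estimated correlation (adjusted p = 0.0453 for each with the latter). Over the set means with an estimated correlation none of the 33 lists was called, and these 3 had an adjusted p of 0.706. With only 4 set means that test has little power, as even the seminal vesicle list with a median of 9.42 was not called. Lists for the unfolded protein response, the nuclear-encoded respiratory chain and ribosomal proteins were lower, and proximal luminal and adipocyte lists higher, with the preset correlation alone. With an estimated correlation their adjusted p ran from 0.198 to 0.595. Of 16197 genes tested, limma called 10670 over the 12 libraries, 5518 higher and 5152 lower in the null. Over the set means it called 662, 349 higher and 313 lower, and all 662 were also called over the 12 libraries. In a simulation, the spread of each gene between sets was set to its estimate from the observed sets. The fit over 12 libraries then called 2794 unchanged genes, 17.5% of them. The fit over set means called 0 but also recovered 0% of 200 genes changed by 1 or 2 on the log2 scale. Such estimates rest on 2 sets per genotype and are imprecise, so these rates need not hold for the real data. In the real data the fit over set means did call genes with differences near 1, such as Sdhc (-1.02) and Bcam (1.09). Differences over 2, or changes in more genes, were not simulated. The 12 libraries did not overlap between genotypes for 7160 genes, 44.2% of those tested, against 0.216% by chance if they were independent. The set means differed with 1 sign in all 4 pairings of a wild-type with a null set for 67.2% of tested genes. By chance that share is 33.3% if the 4 sets were independent. Whether the excess goes beyond chance was not tested. Unadjusted, 11239 genes had a p under 0.05 over the 12 libraries and 5041 over the set means. With the libraries scaled to their totals alone the split was 8611 higher and 2608 lower, and without the 50 most abundant genes it was 6785 higher and 4010 lower. Those scalings moved the median difference of all genes from 0.05 to 0.37 and 0.20, and upper-quartile centring moved it to 0.13.

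**Figure D1:**
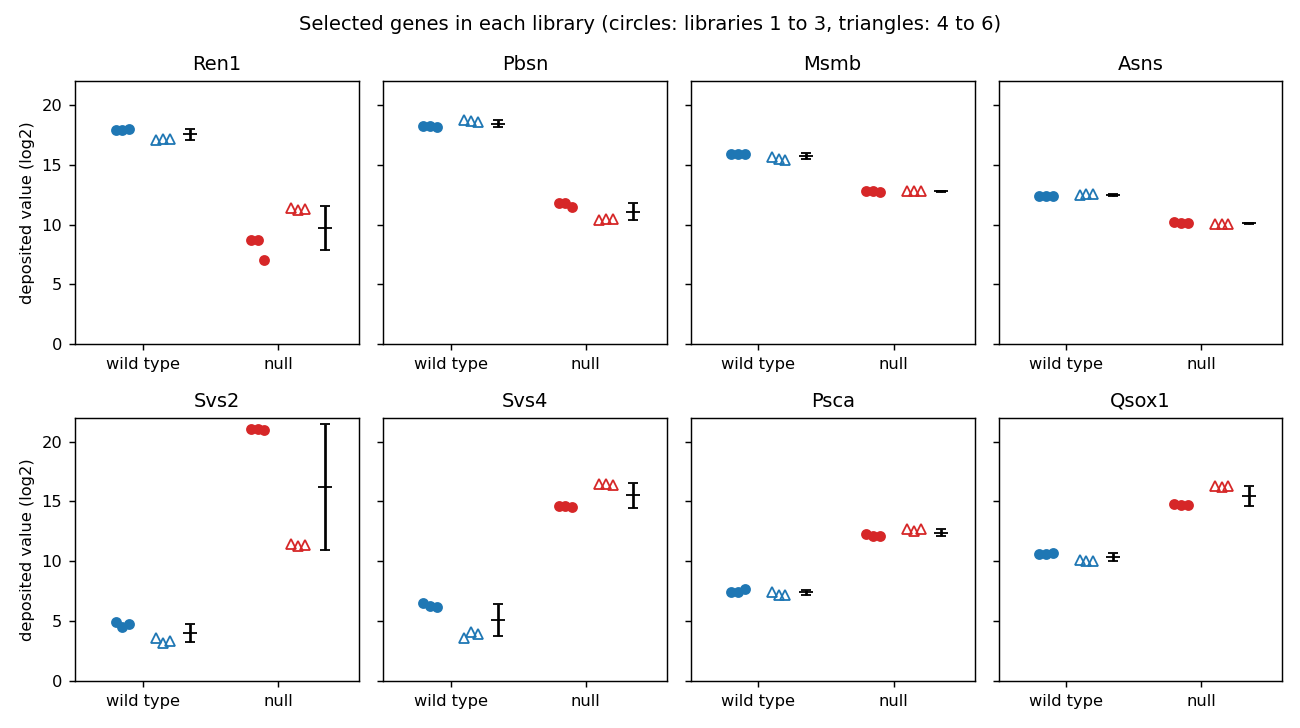
Deposited log2 values (vertical axis) of 8 genes in each of the 6 wild-type (blue) and 6 null (red) libraries; circles are libraries 1 to 3, triangles libraries 4 to 6, and black bars the mean ± SD over 6 libraries. Pbsn has a mean of 18.43 in wild type and 11.06 in the null, and Svs2 differs between the null sets by 9.66.

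Several secreted products of the prostate fell. Pbsn, which encodes probasin (ENSMUSG00000000003, GRCm38 chromosome X, 77837901 to 77853623), had a mean of 18.43 ± 0.28 in wild type and 11.06 ± 0.72 in the null (SD, n = 6 libraries). Pbsn fell by 7.37 (SE 0.54, adjusted p = 0.00632 over the set means). Ren1, which encodes renin and is closely similar to Ren2 in strains that carry both genes, fell by 7.81 (SE 0.96, adjusted p = 0.0147). Whether these mice of hybrid background carried both was not examined, so the value may not be that of Ren1 alone. Msmb, encoding beta-microseminoprotein, fell by 2.92 (SE 0.34, adjusted p = 0.0129). Sbp, encoding spermine binding protein, was at 19.45 ± 0.45 in wild type and 16.08 ± 0.50 in the null, a difference that passed over the 12 libraries (adjusted p = 1.46e-06) and not over the set means (adjusted p = 0.125). The gene with the highest wild-type mean of those tested, 9530053A07Rik, named after its values were seen, was at 21.15 ± 0.06 in wild type and 17.23 ± 0.76 in the null (adjusted p = 8.32e-06 over the 12 libraries and 0.240 over the set means). Of the 13 tested members of the prostate secretory list, 8 were called lower and 1 higher over the 12 libraries, and 4 were lower over the set means (6 when adjusted over the list alone). Itln1 and Crisp1, placed in the list beforehand, did not pass the filter on low values. Crisp1, named after its values were seen, was nevertheless at 14.23 in null libraries 1 to 3 and at 3.61 or lower in each of the other sets. Whether its transcripts in null libraries 1 to 3 came from prostate tissue was not tested. The 4 that fell were Pbsn, Ren1, Msmb and Sbpl, which was named after its values were seen and fell by 3.98 (SE 0.38, adjusted p = 0.00840). The list had a median of -2.27 (camera adjusted p = 0.00196, and adjusted p = 0.0453 with an estimated correlation).

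Other genes with large falls were Ms4a5 (fell by 6.92), Muc19 (fell by 5.77), Fgl1 (fell by 5.73), Pnliprp1 (fell by 5.70) and Olfm4 (fell by 5.57). The mucolipin channel genes Mcoln3 and Mcoln2, which lie side by side on chromosome 3, fell as well. Mcoln3 fell by 5.22, and Mcoln2 was at 11.36 ± 0.06 in wild type and 6.76 ± 0.49 in the null. Mt3, a metallothionein, fell by 5.56, C1s2, a complement component C1s gene, fell by 5.07, and Erich3 fell by 4.86. Their adjusted p over the set means ran from 0.00247 for C1s2 to 0.0346 for Ms4a5.

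Transcripts of the seminal vesicle, the gland that supplies most of the seminal fluid, were low in wild type and higher in the null. Over the 7 named list members, set means were 2.33 for Svs3b to 6.32 for Svs4 in wild type and 7.86 for Pate4 to 21.03 for Svs2 in the null. All 8 tested members of that list were called higher over the 12 libraries and 6 of them over the set means (8 when adjusted over the list alone), with a median of 9.42 (camera adjusted p = 5.67e-06, and adjusted p = 0.0453 with an estimated correlation). Svs4 rose by 10.40 (SE 0.88, adjusted p = 0.00696), Svs5 by 11.77 (SE 1.71, adjusted p = 0.0230), Svs3a by 9.63 (SE 0.66, adjusted p = 0.00632) and Svs3b by 8.74 (SE 0.37, adjusted p = 0.00191). Reads of Svs3a and Svs3b, near-identical neighbours, may have been divided between them. Svs2 had the largest difference, 12.17, yet it was at 21.03 in null libraries 1 to 3 and at 11.37 in null libraries 4 to 6, and it did not pass over the set means (adjusted p = 0.0645). Pate4 (16.73 and 7.86) and Akr1b7 (15.23 and 4.58) were as uneven between the null sets. Genes named Svs took 15.5% to 15.7% of the reads in null libraries 1 to 3 and 0.715% to 0.727% in null libraries 4 to 6. Among the other large rises, Wfdc15b (9.88), Cwh43 (6.91), Wfdc6b (6.49), Wfdc8 (6.47) and Ctse (6.46, cathepsin E) passed both tests.

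Epithelial markers moved in different directions. All 8 genes of the proximal luminal progenitor list were called higher over the 12 libraries and 5 over the set means (7 when adjusted over the list alone), with a median of 2.004 (camera adjusted p = 1.15e-05, and adjusted p = 0.198 with an estimated correlation). Psca rose from 7.40 ± 0.21 in wild type to 12.40 ± 0.28 in the null (SE of the difference 0.24, adjusted p = 0.00191), Clu rose by 3.68 (SE 0.42, adjusted p = 0.0118) and Ppp1r1b by 1.91 (SE 0.21, adjusted p = 0.0112). Ly6a, named after its values were seen, rose by 1.61 (SE 0.25, adjusted p = 0.0265). It was not tested whether the rises in this list share a source with the seminal vesicle transcripts. In the basal list, 8 of 10 were higher and 2 lower over the 12 libraries and 3 were higher over the set means (4 higher and 1 lower when adjusted over the list alone), Trp63 by 1.44, Itgb4 by 1.40 and Bcam by 1.09. Lama3 had a difference of -1.04 (adjusted p = 0.0577 over the set means), against the direction of the basal list (camera adjusted p = 0.0391, and adjusted p = 0.351 with an estimated correlation). The basal epithelium median was no longer called without null library 4 (adjusted p = 0.0517) or 6 (adjusted p = 0.0501), nor with the length trend removed (adjusted p = 0.0884). Of 12 luminal genes, 4 were higher and 6 lower over the 12 libraries, and 1 was lower over the set means (1 higher and 4 lower when adjusted over the list alone). This was Spdef, an epithelial transcription factor gene, which fell by 1.85 (SE 0.18, adjusted p = 0.00881). Among 19 androgen-responsive genes, 9 were higher and 5 lower over the 12 libraries, and the 3 lower over the set means were Tmprss2 (fell by 1.79), Sord (fell by 1.67) and Acsl3 (fell by 1.52), with 1 higher and 3 lower when adjusted over the list alone. As a list they were not called (camera adjusted p = 0.921), nor were the luminal genes (camera adjusted p = 0.229).

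**Figure D2:**
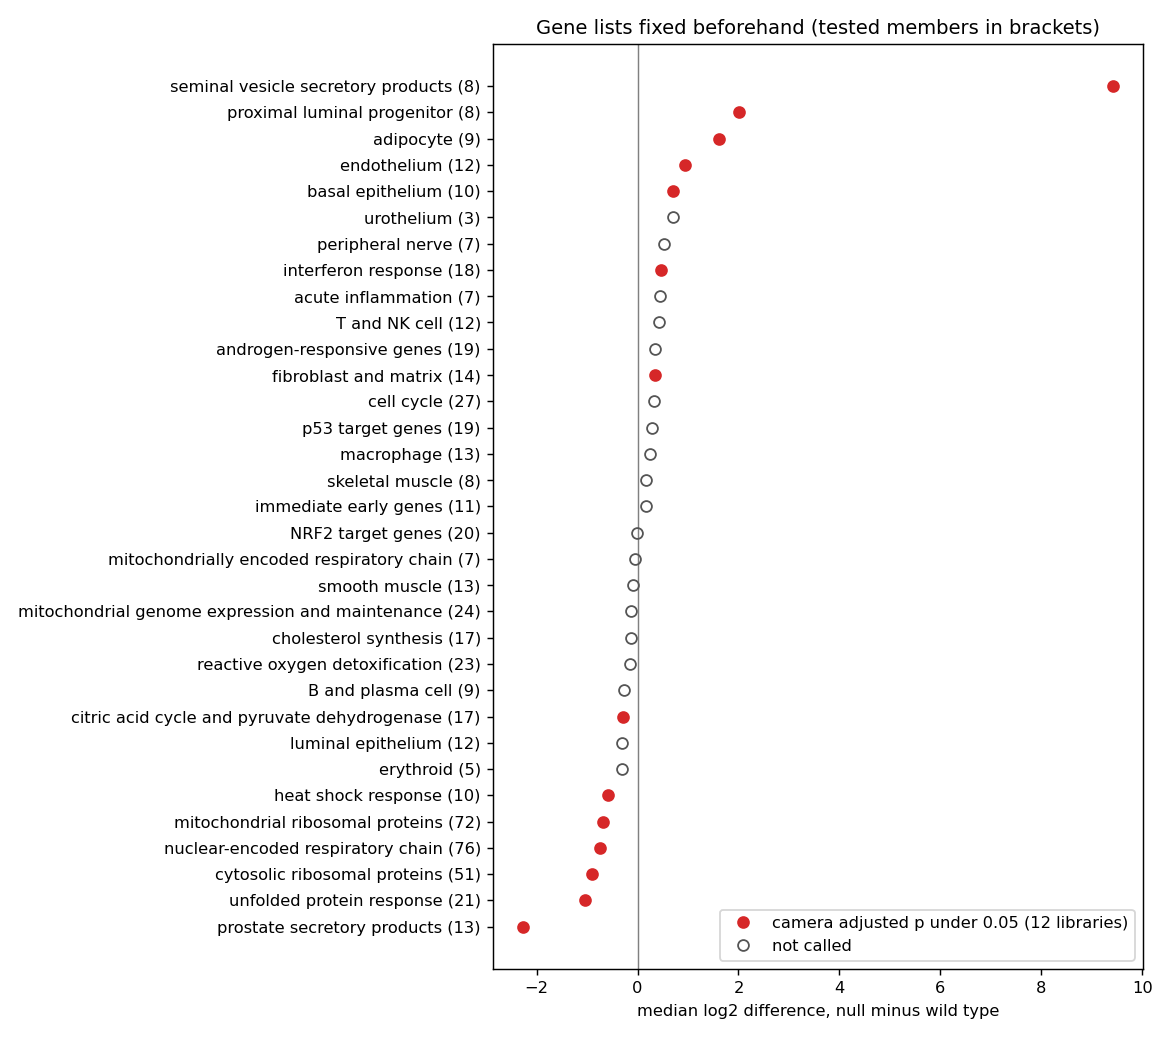
Median log2 difference, null minus wild type (horizontal axis), of the tested members of 33 gene lists fixed beforehand; filled points have a camera adjusted p under 0.05 over the 12 libraries. Seminal vesicle products stand highest at 9.42 and prostate secretory products lowest at -2.27.

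Genes of the respiratory chain were examined because of the mitochondrial subject of the series. Of the 13 protein genes of the mitochondrial genome, 7 could be tested, and mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 did not pass the filter on low values, with a highest value of 5.06 for mt-Co2. How reads that map to several places were handled is not given in the sources used here, so these low values cannot be read as low expression, and the median below covers 7 genes. The 7 had a median of -0.05 and a mean of 0.10 (camera adjusted p = 0.996), and the median was 0.03 with upper-quartile centring and 0.27 with library totals or quantile normalization. It was 0.32 with the length trend removed (adjusted p = 0.116) and -0.18 without the filter on low values (adjusted p = 0.365). All genes of the mitochondrial genome together took 1.58% to 2.07% of the library total in wild-type libraries and 2.36% to 2.69% in null libraries. mt-Nd5 was called higher (0.87) and mt-Nd4 lower (-0.32) over the 12 libraries and neither over the set means, where the adjusted p was 0.237 and 0.620. The remaining differences were 0.44 for mt-Co1, -0.18 for mt-Nd6, -0.16 for mt-Cytb, 0.08 for mt-Nd1 and -0.05 for mt-Nd2, none called in either analysis. With library totals mt-Nd2 was at 0.27, and with the length trend removed mt-Nd6 was at 0.30. Of 76 nuclear-encoded respiratory chain genes, 70 were called lower and 1 higher over the 12 libraries (71 and 1 when adjusted over the list alone). The median was -0.74 (camera adjusted p = 1.08e-11), but adjusted p = 0.584 with an estimated correlation. Over the set means 1 of the 76 was lower, Sdhc of succinate dehydrogenase, which fell by 1.02 (SE 0.19, adjusted p = 0.0445), and 0 were when adjusted over the list alone. Uqcrfs1 (-0.77), Atp5c1 (-0.73) and Sdhd (-0.81) had adjusted p between 0.0853 and 0.0958 over the set means.

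Ribosomal protein genes behaved alike. Of 72 mitochondrial ribosomal protein genes, 61 were called lower and 2 higher over the 12 libraries and 1 was lower over the set means, with a median of -0.69 (camera adjusted p = 4.38e-10, and adjusted p = 0.584 with an estimated correlation). Mrps6 fell by 2.04 (SE 0.32, adjusted p = 0.0274), while Mrpl49, Mrpl43 and Mrps23 differed by -0.69, -0.89 and -0.90 without passing over the set means. Of 51 cytosolic ribosomal protein genes, 43 were called lower and 0 higher, with a median of -0.90 (camera adjusted p = 1.23e-07, and adjusted p = 0.595 with an estimated correlation). Over the set means 1 was lower and 0 when adjusted over the list alone, and Rpl30 fell by 1.83 (SE 0.33, adjusted p = 0.0380). Fau (-1.24), Rpl38 (-1.34) and Rpl32 (-1.36) did not pass there. Ribosomal protein genes have many processed pseudogenes, and their values depend on how shared reads were counted.

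Differences between the genotypes followed transcript length over all genes. The median difference was -0.37 in the quintile of tested genes with the shortest transcripts (median 963 bases) and 0.49 in the quintile with the longest (median 6533 bases). Sets of the same genotype differed along length too, by 0.30 in the shortest and -0.22 in the longest quintile for wild-type libraries 4 to 6 minus 1 to 3. Median transcript length was 1186 bases for the nuclear respiratory chain, 1806.5 for mitochondrial ribosomal proteins and 1120 for cytosolic ribosomal proteins, against 3090.5 for all tested genes. With the length trend removed from every library, the nuclear respiratory chain median was -0.42 (camera adjusted p = 4.36e-08). It was -0.43 with library totals and -0.46 without wild-type libraries 4 to 6, and called in both. These calls used the preset correlation, and with an estimated one camera gave an adjusted p of 0.584 over the 12 libraries.

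**Figure D3:**
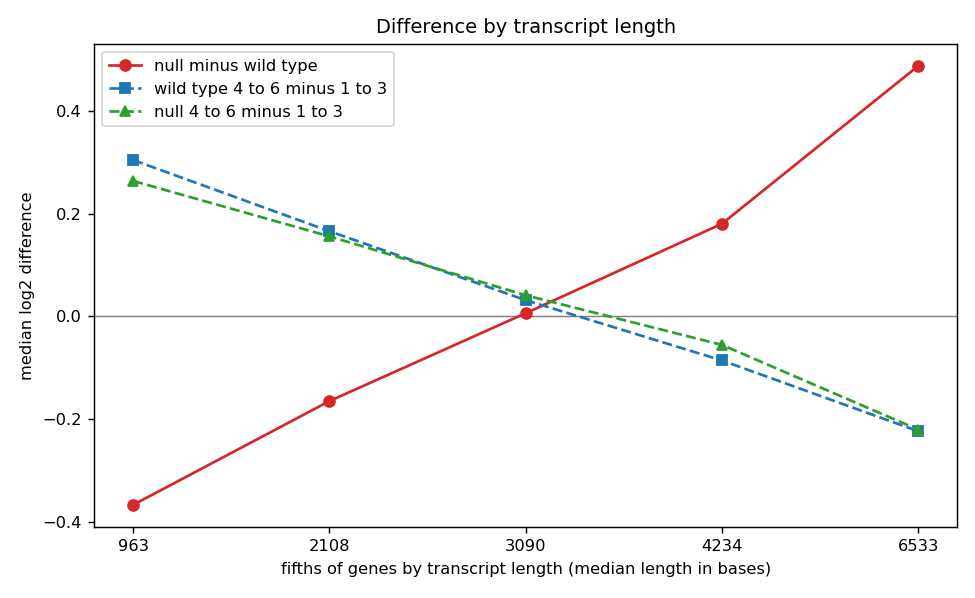
Median log2 difference (vertical axis) of the tested genes in quintiles of transcript length, labelled by the median length in bases (horizontal axis, evenly spaced); the red line is null minus wild type, and dashed lines are libraries 4 to 6 minus 1 to 3 within each genotype. The genotype difference runs from -0.37 to 0.49 from the shortest to the longest quintile.

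Genes of the unfolded protein response were lower in the null. Of 21 tested, 17 were called lower and 0 higher over the 12 libraries and 5 were lower over the set means (10 when adjusted over the list alone), with a median of -1.04 (camera adjusted p = 8.81e-07, and adjusted p = 0.311 with an estimated correlation). Asns, asparagine synthetase, fell by 2.35 (SE 0.19, adjusted p = 0.00632), and Herpud1 fell by 1.82 (SE 0.24, adjusted p = 0.0170). Syvn1, a ubiquitin ligase of the endoplasmic reticulum, fell by 1.45 (SE 0.21, adjusted p = 0.0212), and the transcription factor gene Atf4 fell by 1.41 (SE 0.23, adjusted p = 0.0323). Ddit3, named after its values were seen, fell by 1.84 (SE 0.28, adjusted p = 0.0257). Heat shock genes had a median of -0.58 (camera adjusted p = 0.0391, and adjusted p = 0.584 with an estimated correlation), with 6 of 10 lower over the 12 libraries and 0 over the set means, where Dnajb1, Hspd1, Hsph1 and Hspa8 had adjusted p between 0.119 and 0.140. With the length trend removed, the heat shock response median was no longer called (adjusted p = 0.0751). Among immediate early genes, Egr1 rose by 1.58 while Jun fell by 1.05 and Atf3 fell by 1.17, and Fos differed by 0.73 (adjusted p = 0.156), with 5 of 11 higher and 2 lower over the 12 libraries (camera adjusted p = 0.602).

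Genes of the list for detoxification of reactive oxygen species went both ways. Of 23, 5 were called higher and 10 lower over the 12 libraries and 2 higher and 1 lower over the set means (3 and 5 when adjusted over the list alone), with a median of -0.16, a mean of 0.01 and no call for the list (camera adjusted p = 0.144). Qsox1, a sulfhydryl oxidase that forms disulfides and produces hydrogen peroxide, rose by 5.13 (SE 0.52, adjusted p = 0.00926). Qsox1 was at 14.71 in null libraries 1 to 3 and at 16.25 in null libraries 4 to 6. Whether its rise shares a source with the seminal vesicle transcripts of the null libraries was not tested. Cat, catalase, rose by 0.95 (SE 0.18, adjusted p = 0.0454). The third gene past both tests was Gpx1, glutathione peroxidase 1, named after its values were seen, which fell by 1.65 (SE 0.29, adjusted p = 0.0365). Prdx6, a peroxiredoxin, was at 17.60 ± 0.22 in wild type and 14.72 ± 0.51 in the null (adjusted p = 0.0672 over the set means), and Msra differed by -0.96 (adjusted p = 0.0546). Of 20 NRF2 target genes, 7 were called higher and 7 lower, including Srxn1 (0.69), Osgin1 (-0.87), Ftl1 (-0.71) and Fth1 (-0.90), and 0 passed over the set means (1 higher and 1 lower when adjusted over the list alone). The NRF2 list had a median of -0.01 and a mean of 0.03 (camera adjusted p = 0.996). Of 19 p53 targets, 10 were higher and 3 lower, and Plk2 rose over the set means, by 1.82 (SE 0.35, adjusted p = 0.0464), with Btg2 (0.60), Sesn1 (0.57) and Trp53inp1 (0.40) short of that threshold (camera adjusted p = 0.0620). The p53 target genes median was called without null library 1, 2 or 3, with adjusted p of 0.0473, 0.0461 and 0.0455.

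In the remaining metabolic and growth lists no gene passed over the set means. Citric acid cycle genes had a median of -0.29 (10 of 17 lower and 1 higher, camera adjusted p = 0.01001, and adjusted p = 0.353 with an estimated correlation), with Pdhb at -0.68, Fh1 at -1.06, Suclg1 at -0.64 and Idh3b at -0.47. With library totals the citric acid cycle and pyruvate dehydrogenase median was 0.02 and not called (adjusted p = 0.128). Genes for expression and maintenance of the mitochondrial genome were 5 higher and 9 lower of 24 (camera adjusted p = 0.562), Lrpprc at 0.63 and Ppargc1a at 0.93 against Tsfm at -0.73 and Tfb1m at -0.69. Cell cycle genes were 12 higher and 2 lower of 27 (9 and 2 when adjusted over the list alone, camera adjusted p = 0.0632), Mcm4 at 0.80, Mcm5 at 0.69 and Pcna at 0.39 against Top2a at -0.55. The cell cycle median was called without wild-type library 4 or null library 1, 2 or 3, with adjusted p of 0.0453, 0.0494, 0.0461 and 0.0455. Cholesterol synthesis genes were 3 higher and 8 lower of 17 (1 and 4 over the set means when adjusted over the list alone, camera adjusted p = 0.144), Dhcr7 at -0.94, Msmo1 at -0.52 and Fdps at -1.14.

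Markers of other cell types were also compared. In the adipocyte list, 8 of 9 genes were higher and 1 lower over the 12 libraries and 3 were higher over the set means, Cidec by 2.48, Plin1 by 2.46 and Cfd by 2.16, with Plin4 at 1.11 (8 higher when adjusted over the list alone, camera adjusted p = 0.00519, and adjusted p = 0.452 with an estimated correlation). Endothelial genes were 10 higher and 1 lower of 12 over the 12 libraries (camera adjusted p = 0.00519, and adjusted p = 0.572 with an estimated correlation), with Pecam1 at 0.91, Ptprb at 1.37, Kdr at 1.12 and Flt1 at 1.19 and 0 past the set means, although 8 were higher and 1 lower there when adjusted over the list alone. Fibroblast and matrix genes were 9 higher and 2 lower of 14 (camera adjusted p = 0.0474, and adjusted p = 0.311 with an estimated correlation), with Fn1 at 0.88, Col1a1 at 0.44, Col6a2 at 0.31 and Col1a2 at 0.29, and Col1a2 was at -0.03 with the length trend removed. The fibroblast and matrix median was no longer called without wild-type library 1, 2 or 3 (adjusted p = 0.0670, 0.0628 and 0.0543), nor with median-ratio centring (adjusted p = 0.0519), over the set means (adjusted p = 0.102) or with the length trend removed (adjusted p = 0.238). Smooth muscle genes were 2 higher and 6 lower of 13 (Tagln -0.44, Cnn1 -0.43, Synpo2 0.77, Myocd 1.86, median -0.09, mean 0.05, camera adjusted p = 0.554). Urothelial genes were 2 higher of 3 (Upk2 5.49 in wild type and 7.49 in the null, differences of 0.69 for Upk1b and 0.66 for Upk1a, camera adjusted p = 0.144). Skeletal muscle genes were 2 higher of 8 (Mb 1.93, Ttn 1.27, Ckm 0.61, Acta1 -0.10, camera adjusted p = 0.546), and Acta1 was at 0.22 with library totals. Ttn was at 6.30 in null libraries 1 to 3 and 3.80 in 4 to 6 (3.57 and 3.98 in the wild-type sets), and Ckm at 8.67 and 6.80 (7.13 and 7.12). Synpo2 (11.52 and 10.60) and Upk1a (11.84 and 13.41) were also uneven between the null sets. The gene Ttn was not called without any 1 of wild-type libraries 1 to 6 or null libraries 1 to 3, with adjusted p of 0.0556 to 0.105. Nerve genes were 3 higher of 7 (Cdh19 1.61, Pmp22 0.52, Sox10 0.69, camera adjusted p = 0.474), and the 3 named here were higher in null libraries 1 to 3 than in 4 to 6 (Cdh19 6.80 and 4.90, Pmp22 9.81 and 8.93, Sox10 6.33 and 5.14). The gene Pmp22 was not called without wild-type library 5 or 6 or null library 1, 2 or 3 (adjusted p from 0.0503 to 0.0593). The gene Sox10 was called without null library 4 (adjusted p = 0.0328) or 6 (adjusted p = 0.00796), and the gene Upk1a without null library 1, 2 or 3 (adjusted p from 0.0333 to 0.0416).

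Interferon-response genes were higher in the null. Of 18, 14 were called higher and 1 lower over the 12 libraries, with a median of 0.46 (camera adjusted p = 0.00124, and adjusted p = 0.0453 with an estimated correlation), and over the set means Ddx58, an RNA sensor gene, rose by 1.41 (SE 0.21, adjusted p = 0.0244). Adjusted over the list alone, 3 were higher over the set means. Oasl2 and Mx2 differed by 0.77 and 1.33, and Ifi44 was at 5.81 ± 0.18 in wild type and 6.81 ± 0.20 in the null. Of 7 acute inflammation genes, 3 were higher, and Lcn2, lipocalin 2, rose by 2.73 (SE 0.29, adjusted p = 0.0107). Ptgs2, in contrast, was at 12.37 in null libraries 1 to 3 and 5.06 in null libraries 4 to 6. Akr1b7 (15.23) and Crisp1 (14.23), outside this list, were also high in null libraries 1 to 3 alone. Whether Ptgs2 shares a source with them was not tested. Saa3 was at 4.98 in null libraries 1 to 3 and 7.39 in null libraries 4 to 6, against 4.57 and 4.46 in the wild-type sets. Saa3 and Il1b differed by 1.67 and 0.45 (camera adjusted p = 0.227 for the list). Macrophage genes were 6 higher of 13 (Mrc1 1.14, Csf1r 0.59, Adgre1 0.77, camera adjusted p = 0.0979), called without null library 1 or 3 (macrophage median, adjusted p = 0.0473 and 0.0455), and T and NK cell genes 3 higher of 12 (Cd8a 1.26, Zap70 0.77, Gzma 0.45, camera adjusted p = 0.171). The gene Gzma was called without wild-type library 2 or 3 (adjusted p = 0.0304 and 0.0225). Jchain (1.24) was the 1 of 9 B and plasma cell genes called, with Ms4a1 at -0.36, Pax5 at -0.52 and Cd79b at -0.32 (median -0.26, camera direction higher, adjusted p = 0.996). Cd79b was at 5.96 in wild-type libraries 1 to 3 and 8.42 in 4 to 6. Without wild-type libraries 4 to 6 the B and plasma cell median was 0.90 (adjusted p = 0.0249), and without libraries 1 to 3 it was -1.10 (adjusted p = 0.0427). Of the erythroid genes, Alas2 (0.80) was the 1 of 5 called, with Hba-a1 at -0.60, Hba-a2 at -0.35 and Hbb-bt at -0.30 (camera adjusted p = 0.921). In all, camera called 14 of the 33 lists, 7 higher and 7 lower, of which prostate secretory products, seminal vesicle products and interferon response held with an estimated correlation over the 12 libraries. Over the set means camera called 13 with the preset correlation and 0 with an estimated one, where these 3 had an adjusted p of 0.706, and fry called 0 (adjusted p = 0.0870 for each of the 3).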

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

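Among 368 groups of 6 values examined for a library far from the others, 4 had one. Chance would give 18.4, or 1 in 20, if the 6 values were independent, but each group is made of 2 sets of 3 similar libraries, so the counts are not comparable. Akr1b7 was at 1.33 in wild-type library 3 and at 2.48 to 3.03 in the other wild-type libraries, and Cwh43 was at 1.53 in wild-type library 6 against 3.28 to 4.10. Il1b was at 3.35 in wild-type library 6 against 4.34 to 4.89. The median of the heat shock list was 10.55 in wild-type library 4 against 10.19 to 10.32.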

How the results depend on the processing

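The set means, the set as a random block, leaving out a set, quantile normalization, the stricter filter, the damped scale and removal of the length trend were chosen after seeing the data. The median of the nuclear respiratory chain stayed negative throughout (-1.01 to -0.42), but its call was lost with an estimated correlation (-0.74, adjusted p = 0.584) and with set means and an estimated correlation (-0.74, adjusted p = 0.706). Leaving out 1 library gave 9957 to 10696 called genes, and leaving out a set 8852 to 11901. Requiring a change of at least 1 gave 2655 genes (1723 higher, 932 lower), the set means 662 (349 and 313), the random block 5052 (2285 and 2767) and set means without the length trend 828 (400 and 428). Library totals gave 8611 higher and 2608 lower. Of the 33 lists, 22 were called without the filter, 3 with an estimated correlation, 25 by fry, which does not compare a list with other genes, and 0 with set means and an estimated correlation. With library totals the citric acid cycle and pyruvate dehydrogenase median was 0.0206, gene mt-Nd2 0.27 and gene Acta1 0.22, and Acta1 was 0.15 with quantile normalization. Without the length trend gene mt-Nd6 was 0.30, Acta1 0.19 and gene Col1a2 -0.0286, the last also with set means. Without wild-type libraries 4 to 6 the B and plasma cell median and gene Cd79b were both 0.90. The causes were not tested. The mitochondrially encoded list had no value without the 50 highest genes, which left too few members. Alternatives that need counts (TMM, DESeq2, voom and a minimum of 10 counts) were not run. With set means 70 of 154 named genes stayed on the same side of the threshold, whether called or not, and 84 lost their call. Depth limits genes near the floor, where values are not proportional to reads.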

Other observations

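Of the tests below, those on transcript length and GC content were fixed before their results were seen, and the others were chosen afterwards. Outside the lists, the metallothionein genes Mt1 and Mt2, which encode metal-binding proteins induced by metals and oxidants and were named after their values were seen, fell along with Mt3. Mt1 fell by 3.50 (SE 0.33, limma adjusted p = 0.00800 over the set means) and Mt2 by 3.35 (SE 0.28, adjusted p = 0.00696). Of the 12 genes with the highest rises, 8 lay in a stretch of chromosome 2 (GRCm38, 164214454 to 164618212) that holds Svs and Wfdc genes. Of 19 tested genes in that stretch, 15 were called higher and 1 lower over the 12 libraries, and 10 rose in both analyses. The stretch was chosen because of those rises, so these counts are descriptive.

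The call count was compared with other groupings of the libraries. Of 100 splits out of 462, 1 called as many genes as the real split, the real one itself, with 10670 genes against a highest other of 6583. This ranking cannot exclude chance, because the random splits mostly break up sets of closely similar libraries that were not shown to be independent. The median of the random splits was 0. Splits that keep the sets whole called 654 genes (libraries 1 to 3 of both genotypes against 4 to 6) and 220 genes. With only 3 such splits of 4 sets, no share under 0.05 can be had at the level of sets.

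Seminal vesicle transcripts in the null libraries were weighed first. A single admixed source of fixed profile is argued against by the difference between the null sets, which ranged over 11.53 between list members, with Svs2 at 9.66 and Svs3a at -1.87 (libraries 1 to 3 minus 4 to 6). For scaling by a few abundant genes, the list median was at least 9.41 over the scalings run. Those scalings gave a median over all genes of -0.04 to 0.37, too little to lower the list median far. The result thus argues only against a scaling error of about that size. Seminal vesicle tissue of varying makeup in the null samples stays open, with 8 of the 9 list members called higher. The remaining one, Svs1, did not pass the filter on low values and was at no more than 5.35 in any library. Its mean was 5.27 in null libraries 1 to 3, 2.23 in null libraries 4 to 6, and 3.12 and 1.94 in the wild-type sets. No sample of seminal vesicle was used here to settle that source, and expression by the null prostate itself stays open too, as untested.

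The sets of 3 libraries were weighed next. Repeated sequencing of a single library in each set stays open, since the lowest median chi-square within a set was 0.987, above simulated counting noise alone (0.382 to 0.543), to which runs or lanes would add. Depth is argued against in the null, where the depth ranges of the sets overlapped (gap -1.36 M reads), and also in wild type, although the ranges there were 1.86 M reads apart. Pairs from different wild-type sets whose depth differed by no more than that of some pair within a set (3.47 M reads) had a median chi-square of at least 42.4, which was 7.43 times the highest within a set. Separate preparations of the same RNA, or sets from different animals or pools, may account for the sets and were not tested, as nothing in the labels separates them.

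The joint fall of the nuclear respiratory chain and both ribosomal protein lists (199 genes, median -0.76) was weighed against sequence properties. Random lists matched on transcript length and mean level had a median of -0.45 (95% range -0.56 to -0.36). Transcript length may thus account for part of the fall, though 0% of 10000 such lists fell as far. For lists matched on GC content and level the median was -0.10, and 0% fell as far. The estimated correlation between genes was 0.82 in the nuclear respiratory chain, 0.70 in mitochondrial and 0.84 in cytosolic ribosomal proteins. The random lists were not matched on this correlation, and lists of genes that move together can spread more widely. The shares of 0% therefore cannot decide whether the fall goes beyond transcript length or GC content. Spread between sets stays open, because the smallest fall over the 4 pairings of a wild-type with a null set was -0.25, less than the difference of 0.53 between the wild-type sets. An effect of the genotype on these genes beyond transcript length is thus a hypothesis that these 4 sets cannot settle.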
